A study of Mus musculus with 9 samples.

How the data were processed

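Labelled RNA of 9 samples of mouse colonic mucosa was hybridised to Agilent 1-colour arrays of design 014868, 1 array per sample. Per the file headers, the intensity values are green-channel processed signals, from which Feature Extraction software had subtracted background, and the median spot and background intensities stand beside them. The whole-series table deposited by the authors holds log2 values of 23726 probes. Set against the scanner files, each of its columns equalled the log2 processed signal minus that array's median over all probes, with r of at least 0.999993. Its column medians ran from 2.36 to 2.8, and 99.9% of its probes were well above background on every array. How its probes were chosen is not given in the sources used here, and it served as an alternative. The scanner files were annotated on mouse build mm9.

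From the deposited intensities, log2 of the processed signal was taken and each array's 75th percentile subtracted, which centres the arrays on their upper signals. That percentile ran from 572.5 to 819.2 and the median local background from 33.5 to 50. Control spots and outlier spots were left out, the latter touching 188 probes, and 0 spots were saturated. Of 41174 probes, 27207 were kept as well above background on all 3 arrays of at least 1 group. The files used here held no gene symbols, so probes were named by their transcript accession through a RefSeq table of assembly GRCm38.p6, from which no coordinates were taken. In this way 25097 probes had 1 symbol (17305 symbols) and 16077 stay unnamed here. The brightest kept probe stood for each gene, which gave 21094 features, 14192 with a symbol and 6902 unnamed. Several kept probes were present for 4635 symbols.

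Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 9 arrays sharing 1 estimate of the spread), with Benjamini-Hochberg adjustment at 0.05 within each of 4 contrasts. These were the mean of both high calcium groups against DMH, each against DMH, and both against each other. A difference is in log2 units with its standard error from this fit, n = 3 arrays per group. A gene not well above background on any array of a group has only a loose bound. It is printed as at least N-fold, also where that group is 1 of the 2 in a mean. The bound sets the brighter group's mean against, for each dim array, the higher of the gene's own signal and the lowest one well above background there. Another background correction put some genes below it. Gene lists (36, of which 35 had at least 4 measured members) were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over all lists and contrasts. Camera with an estimated correlation and fry, which asks whether the genes of a list move 1 way on balance, were run beside it.

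Groups, lists, tests, the alternatives unless said otherwise, and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest rises and 10 largest falls of a contrast (8 and 8 for both high calcium groups) among genes past the threshold whose arrays do not overlap. It adds up to 4 members past the threshold per list and contrast, for a list past camera's threshold up to 4 of its members with the largest change in the direction of the list, and a panel of 16 genes given in every contrast. Of that panel, Casr and Axin2 failed the background filter, and Muc2 and Mgmt had no probe named here. Between 156 and 167 genes per contrast met the rule, and those printed are a choice from them. A few genes that met it are not reported here.

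Slide was tested as a batch from the array positions in the files. As groups shared slides 1 and 2, each value was also fitted with the slide as a block. Other alternatives were normexp background correction (on the median spot signal, since a mean signal was not among the columns used, offset 50), quantile normalization, the whole-series table, no filter on dim probes, a filter asking for all 9 arrays, the mean of a gene's probes, every probe tested by itself, a trended and robust fit, array weights, only the compared groups in the fit, the replicate number as a block, an unadjusted p under 0.05 with a 2-fold change, and each array left out in turn. Where leaving arrays out left 1 array of a group on a slide, that array was assumed to vary like the others.

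In simulated data 200 of 21012 genes changed by 0.5, 1 or 2 (log2). Against DMH, recovery was 59.7, 71.6 and 80.3% for both groups, 38.8, 71.6 and 86.4% without tumors and 47.8, 61.2 and 84.8% with tumors. Between the high calcium groups it was 37.3, 61.2 and 87.9%. Of the calls 7.2, 5.6, 3.4 and 7.7% were unchanged genes. These rates may not hold with slide effects or 6663 to 10028 calls, as here.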

Results

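The series concerned the protection against colorectal cancer that is attributed to dietary calcium. Gene expression was measured in total RNA of colonic mucosa, labelled as normal, from ICR mice, an outbred stock. Every group had received 1,2-dimethylhydrazine (DMH), a carcinogen that produces colon tumors in rodents, under the skin at 20 mg/kg each week for 20 weeks. The 9 arrays fell into 3 groups of 3. A group on a diet with 3% calcium had no tumors, a group on the same diet had tumors, and a group on a diet with 1.24% calcium is called DMH here after its label. The tumor status of the DMH group is labelled only as control, so whether those mice carried tumors is not given in the sources used here. Nothing in the labels says whether the 3 arrays of a group came from separate mice, so p-values measure only the spread between these arrays, which may be technical. On each array 61.1 to 73.8% of 41174 probes were well above background (25153 to 30374 probes), and no spot was saturated. The number of arrays limits the precision of every value.

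Arrays of 1 group on 1 slide resembled each other most. Across tested genes, which are not independent replicates, Pearson's r was 0.994 to 0.997 in 5 such pairs, with 118 to 445 genes at least 2-fold apart. In 4 pairs of the same group on different slides r was 0.967 to 0.985, with 1166 to 2923 such genes. In 7 pairs of different groups on the same slide it was 0.979 to 0.983, with 1110 to 1600. Slide 1 held the 3 arrays without tumors and DMH replicate 1. Slide 2 held replicates 1 and 2 with tumors and DMH replicates 2 and 3, and slide 3 replicate 3 with tumors alone. The first principal component carried 50.3% of the variance, of which slide accounted for 92.1% and group for 64.8%. The second carried 21%, with 93.2% for group and 45.3% for slide. For feature counts and for the medians of lists that passed, values with the slide as a block or within a slide therefore stand beside those without. For genes that passed they are given where the block ended a call or moved a fold by over 1.5 times. Within slide 1 the 3 arrays without tumors were set against DMH replicate 1, and within slide 2 those with tumors against 2. No slide held both high calcium groups, so the block linked them through these DMH arrays, without replicate 3 with tumors.

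**Figure D1:**
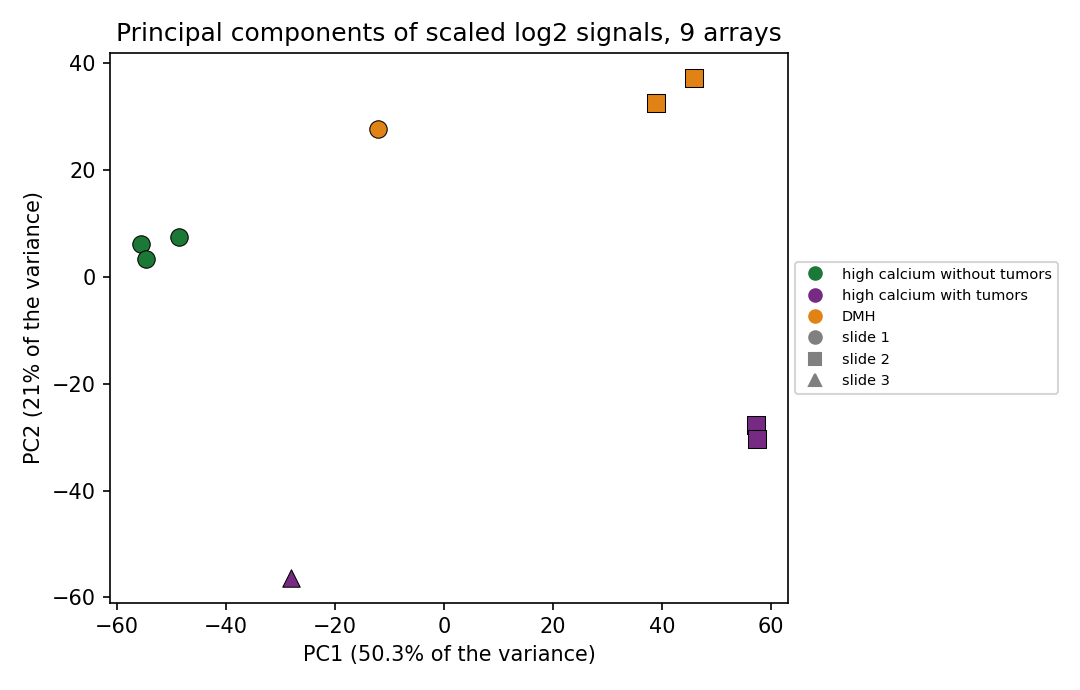
First and second principal components of the scaled log2 signals of the tested genes on the 9 arrays, with axes in component units, colour for group and marker shape for slide. The first component (50.3% of the variance) parts slide 2, at the right, from slide 1 and the single array of slide 3, which lies within the range of slide 1. The second (21%) orders the groups.

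The first comparison asked how mucosa on the high calcium diet, as the mean of both groups, differed from that of the DMH group. Among named genes well above background on some array of every group, the largest falls that passed were those of Adipoq, Cfd, Cxcl5 and Car3. Cxcl5, a chemokine that attracts neutrophils, was 27.7-fold lower on high calcium (log2 difference -4.79 ± 0.13 SE, n = 3 arrays per group, adjusted p = 1.86e-06). Its scaled log2 signals were -4.61 ± 0.2 (SD) without tumors, -3.1 ± 0.25 with tumors and 0.93 ± 0.09 in DMH. Its relative Cxcl3 was not well above background on any high calcium array and was at least 3.53-fold lower there (adjusted p = 7.9e-05). That call ended under normexp background correction (adjusted p = 0.0575). Adipoq, the adipocyte hormone adiponectin, fell 38.3-fold (-5.26 ± 0.72, adjusted p = 0.0016) and Car3, a carbonic anhydrase abundant in fat, 26.1-fold (-4.71 ± 0.62, adjusted p = 0.00136). Adipoq was well above background on 2 of the 3 arrays without tumors, as was Cfd, the adipocyte protein adipsin. Mrap, a melanocortin receptor accessory protein of adipose tissue, and Cacna1f, a voltage-gated calcium channel subunit, were not well above background on any array without tumors, and on 2 and 1 with tumors. They were at least 8.37-fold and 7.51-fold lower (adjusted p = 0.00424 and 0.000145). Cfd differed by -5.24 ± 1.39 (adjusted p = 0.0252). That call ended without replicate 1 or 2 with tumors (adjusted p = 0.0523 each) or without DMH replicate 1, 2 or 3 (adjusted p = 0.0598, 0.0749 and 0.0825). Without both DMH replicate 1 and replicate 3 with tumors its adjusted p was 0.0529, and without replicate 1 of the group without tumors its difference was -4.18. Cyp2e1, a cytochrome P450 that takes part in activating DMH, was not well above background on any high calcium array and was at least 6.42-fold lower (adjusted p = 0.000895).

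The largest rises included clock genes. Gdpd3, of the glycerophosphodiester phosphodiesterase family, was 18.5-fold higher on high calcium (4.21 ± 0.5, adjusted p = 0.00092) and Camk2n1, an inhibitor of calcium/calmodulin-dependent kinase II, 6.31-fold (2.66 ± 0.32, adjusted p = 0.000906). Per2 and Per3, repressors in the circadian clock, were 4.16-fold and 3.52-fold higher (2.06 ± 0.08 and 1.82 ± 0.05, adjusted p = 1.59e-05 and 2.72e-06). Abcg5, part of a sterol exporter, Casp14, a caspase of epidermal differentiation, and Nat8f5 were 4.05-fold, 3.82-fold and 3.48-fold higher (adjusted p at most 0.000117), with Nat8f5 well above background on 1 of 3 DMH arrays. Myt1l was not well above background on any DMH array and was at least 1.18-fold higher (adjusted p = 0.0196). Its difference was -0.01 under normexp correction, and its adjusted p was 0.0555, 0.0581 and 0.0628 without DMH replicates 1, 2 and 3, and 0.0504 without both DMH replicate 1 and replicate 3 with tumors. Of the clock list 10 of 18 genes rose and 3 fell (11 and 3 adjusted over the list alone), with Tef (1.57 ± 0.09) and Dbp (1.39 ± 0.14) among those that rose. The list's median was 1 (adjusted p = 0.00446, and adjusted p = 0.455 with an estimated correlation), and 1.01 with the slide as a block.

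Trpv6 and S100g, genes of calcium uptake, were lower on the high calcium diet. Trpv6, the epithelial calcium channel, fell 3.51-fold (-1.81 ± 0.08, adjusted p = 2.57e-05), and S100g, the calcium carrier calbindin-D9k, 1.65-fold (-0.72 ± 0.08, adjusted p = 0.000588). Stc1, the secreted glycoprotein stanniocalcin 1, fell 2.37-fold (-1.24 ± 0.22, adjusted p = 0.00503), but not under normexp correction (adjusted p = 0.0704). Vdr, the vitamin D receptor, rose by 0.23 ± 0.06 (adjusted p = 0.017). The call ended without DMH replicate 3 (0.19, adjusted p = 0.0755), under normexp correction (adjusted p = 0.059), on the series matrix values (adjusted p = 0.726), without the filter on dim probes (adjusted p = 0.0518) and with the replicate block (adjusted p = 0.0525). Cyp24a1, which breaks down vitamin D hormone and was well above background on 3 arrays without tumors, 1 with tumors and 2 of DMH, differed by 0.1 ± 0.4 (adjusted p = 0.86). Casr, the calcium-sensing receptor, and Axin2 were well above background on only 3 and 1 of the 9 arrays and were not tested. As a list, calcium and vitamin D handling did not pass (3 of 17 genes rose and 5 fell, 3 and 6 adjusted over the list alone, median -0.05, adjusted p = 0.23).

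Cell cycle genes and Wnt targets fell together. Of 30 proliferation genes 17 fell and 0 rose (19 and 0 adjusted over the list alone), including Top2a (-0.89 ± 0.09), Ube2c (-0.75 ± 0.08) and Mki67 (-0.6 ± 0.07), all at adjusted p of at most 0.00109. The median was -0.62 (adjusted p = 1.87e-10, and adjusted p = 0.455 with an estimated correlation), or -0.59 with the slide as a block. Of 19 Wnt targets and crypt stem cell genes 11 fell and 1 rose (12 and 2 adjusted over the list alone), led by Sp5, a transcription factor induced by Wnt signals (-1.87 ± 0.06), Notum, an enzyme that inactivates Wnt proteins (-1.78 ± 0.1), and Nkd1, another feedback inhibitor (-1.15 ± 0.05). This list's median was -0.43 (adjusted p = 1.98e-06, and adjusted p = 0.453 with an estimated correlation), or -0.38 with the slide as a block. Myc fell 1.41-fold (-0.5 ± 0.05, adjusted p = 0.00033). The stem cell marker Lgr5 (-0.05 ± 0.05, adjusted p = 0.494) and the cell cycle inhibitor Cdkn1a (0.13 ± 0.07, adjusted p = 0.182) did not pass. Cdkn1a passed without DMH replicate 1 (0.2, adjusted p = 0.0469) and with array weights (0.19, adjusted p = 0.0285). DNA repair genes fell in 8 of 24 cases (9 adjusted over the list alone), among them Brca1 of double-strand break repair (-0.5 ± 0.06), with a median of -0.12 (adjusted p = 0.000461, and adjusted p = 0.455 with an estimated correlation) or -0.1 with the slide as a block.

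Genes of inflammation and of several immune cells were lower on high calcium. In the list of inflammation and antimicrobial defence 14 of 24 genes fell and 5 rose (16 and 6 adjusted over the list alone, median -0.39, adjusted p = 0.000128, and adjusted p = 0.182 with an estimated correlation, slide-block median -0.56). Lcn2, which withholds iron from bacteria, fell 7.47-fold (-2.9 ± 0.13), and Ptgs2, the inducible cyclooxygenase, 2.58-fold (-1.37 ± 0.12, adjusted p = 0.000298). Cxcl2 was not well above background on any high calcium array and was at least 2.69-fold lower (adjusted p = 4.43e-05), which did not hold under normexp correction (adjusted p = 0.189). Myeloid genes fell in 8 of 19 cases and rose in 1 (13 and 1 adjusted over the list alone), among them the calprotectin subunits S100a9 (-3.1 ± 0.08) and S100a8 (at least 8.34-fold lower, adjusted p = 2.7e-05, on 0 arrays without tumors well above background). Of 9 mast cell genes 5 fell by either count, those adjusted over the list alone included, led by the mucosal proteases Mcpt2 (-2.04 ± 0.07) and Mcpt1 (-1.92 ± 0.08) and the carboxypeptidase Cpa3 (-1.74 ± 0.1). Of 17 B and plasma cell genes 10 fell (13 adjusted over the list alone), among them Mzb1 (-0.5 ± 0.07). Medians of these 3 lists were -0.22, -1.4 and -0.35 (adjusted p = 5.79e-06, 0.000159 and 6.3e-06, and adjusted p = 0.325, 0.182 and 0.455 with an estimated correlation), and -0.23, -1.33 and -0.35 with the slide as a block. Matrix metalloproteinases named in the list of colorectal tumour genes fell, Mmp10 8.49-fold, Mmp7 6.34-fold and Mmp9 4.25-fold (-3.09 ± 0.07, -2.66 ± 0.05 and -2.09 ± 0.08), though that list as a whole did not pass (5 of 26 genes rose and 7 fell, the same counts adjusted over the list alone, adjusted p = 0.129).

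Markers of tissue layers other than epithelium moved as well. Of 15 smooth muscle genes 14 rose (15 adjusted over the list alone), such as Des and Synm, the filament proteins desmin and synemin (1.22 ± 0.17 and 1.2 ± 0.2), and 4 of 12 genes of enteric neurons and glia rose (6 adjusted over the list alone), such as the neuropeptide genes Vip (1.15 ± 0.08) and Tac1 (0.83 ± 0.11). Medians were 0.96 and 0.59 (adjusted p = 5.79e-06 and 0.0369, and adjusted p = 0.534 and 0.738 with an estimated correlation). With the slide as a block they were 0.89 and 0.47, and the call of the neuronal list ended (adjusted p = 0.115). It also ended without replicate 2 with tumors and without DMH replicate 1 or 2. Adipocyte genes fell in 10 of 11 cases, adjusted over the list alone too, and squamous epithelium genes in 8 of 13 with 1 that rose, adjusted over the list alone too, Krt14 among them (-1.77 ± 0.07). Their medians were -2.75 and -0.59 (adjusted p = 1.61e-05 and 0.00141, and adjusted p = 0.472 and 0.455 with an estimated correlation), or -3 and -0.51 with the slide as a block. Fatty acid oxidation and ketogenesis fell in 8 of 20 genes, adjusted over the list alone too, including the fatty acid transporter Cd36 (-1.3 ± 0.2). Immediate early and stress genes fell in 8 of 22 cases and rose in 2, adjusted over the list alone too, with Ier3 (-1.39 ± 0.12) and Egr1 (-0.9 ± 0.07) among them. Medians of these 2 lists were -0.19 and -0.05 (adjusted p = 0.000479 and 0.0297, and adjusted p = 0.534 and 0.455 with an estimated correlation), or -0.23 and -0.06 with the slide as a block, and the second call ended without DMH replicate 1. The colonocyte genes Aqp8 (0.24 ± 0.18, adjusted p = 0.352) and Krt20 (0.16 ± 0.11, adjusted p = 0.316) did not pass, although Aqp8 passed without both DMH replicate 1 and replicate 3 with tumors (0.3, adjusted p = 0.0481), a setting chosen after seeing the data.

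In all, 3762 features were higher and 2901 lower in the mean of both groups among 21094 tested. Of these 225 and 356 differed at least 2-fold. With both groups taken as 1 group, 1942 features passed. With the slide as a block the mean gave 8190, 6264 also without it and with the same sign. Of those at least 2-fold apart 98.8% kept their call. Camera called 14 of 35 lists, 3 up and 11 down, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05. The squamous call ended on the series matrix values and among probes well above background on all 9 arrays. With array weights the neuronal and immediate early calls ended. Without DMH replicate 3 there were 4320 features. Of the calls 56.5% were higher, against 30.3% on the series matrix values, 49.4% after quantile normalization and 40.4% at unadjusted p under 0.05 with 2-fold. Under normexp correction many differences were smaller, Cxcl5 at -3.33, Adipoq -3.34, Car3 -3.74, Cfd -4.39 and Gdpd3 3.02, and those of Mrap (-1.02), Cacna1f (-0.84), Cyp2e1 (-0.98) and S100a8 (-1.26) lay below their bounds. Camk2n1 was then at 1.75, Per3 0.9, Nat8f5 0.52, Lcn2 -1.51, Mcpt2 -1.45, Cpa3 -0.94, Ptgs2 -0.76 and Mmp9 -1.27. With the mean of its probes Per2 was at 1.31.

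The second comparison set high calcium mice without tumors against DMH. Wnt targets and proliferation genes fell, and genes of absorptive cells and of cholesterol synthesis rose. Sp5 fell 8.84-fold (-3.14 ± 0.08, adjusted p = 1.51e-06), Notum 8.35-fold (-3.06 ± 0.11), Nkd1 4.28-fold (-2.1 ± 0.05) and Lgr5 1.59-fold (-0.67 ± 0.06). Of 19 genes of this list 13 fell and 1 rose, the same counts adjusted over the list alone, with a median of -0.61 (adjusted p = 4.82e-07, and adjusted p = 0.453 with an estimated correlation) and -0.55 within slide 1. Of 30 proliferation genes 20 fell and 1 rose (20 and 2 adjusted over the list alone), such as the mitotic kinases Plk1 (-1.1 ± 0.1) and Aurka (-1.07 ± 0.08) and also Mki67 (-0.83 ± 0.09). Their median was -0.82 (adjusted p = 3.87e-07, and adjusted p = 0.455 with an estimated correlation) and -0.73 within slide 1. Myc fell 1.53-fold (-0.61 ± 0.05), and DNA repair genes fell in 9 of 24 cases, adjusted over the list alone too (median -0.14, adjusted p = 0.000461, and adjusted p = 0.455 with an estimated correlation, -0.15 within slide 1). Of 18 p53 targets 9 fell and 1 rose (10 and 1 adjusted over the list alone), among them Plk2 (-1.03 ± 0.11) and Phlda3 (-0.8 ± 0.06), while Cdkn1a, the best known target, differed by 0.01 ± 0.08 (adjusted p = 0.95). The median of this list was -0.21 (adjusted p = 0.0125, and adjusted p = 0.534 with an estimated correlation), or -0.17 within slide 1. Its call ended on the series matrix values and with the mean of the probes of a gene.

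Absorptive colonocyte genes rose in 14 of 24 cases and fell in 1, the same counts adjusted over the list alone. Aqp4, a water channel, was 3.42-fold higher (1.78 ± 0.1), Slc26a3, the chloride/bicarbonate exchanger, 2.4-fold (1.26 ± 0.11), and Car4, a membrane carbonic anhydrase, 2.29-fold (1.2 ± 0.11). Cdx2, a transcription factor of intestinal identity, was the gene that fell (-0.75 ± 0.08). Aqp8 was 1.59-fold higher (0.67 ± 0.21, adjusted p = 0.0419). Its call ended within slide 1 (0.34, adjusted p = 0.115), under 5 other planned settings and in 6 of the 9 fits that left out an array. These left out each array without tumors (adjusted p = 0.0954 to 0.105), replicate 2 with tumors (adjusted p = 0.0635) and DMH replicates 2 and 3 (adjusted p = 0.12 and 0.133). Krt20 did not pass (0.28 ± 0.13, adjusted p = 0.127), but did with array weights (adjusted p = 0.0115) and without both DMH replicate 1 and replicate 3 with tumors (adjusted p = 0.0145). Of 19 cholesterol synthesis genes 13 rose and 0 fell (14 and 0 adjusted over the list alone), including Insig1 (0.61 ± 0.06) and Sqle (0.54 ± 0.04). On the series matrix values, centred differently, Insig1 and Sqle no longer passed (adjusted p = 0.0965 and 0.145). Medians of the colonocyte and cholesterol lists were 0.38 and 0.29 (adjusted p = 0.00112 and 5.76e-05, and adjusted p = 0.472 and 0.453 with an estimated correlation), or 0.27 each within slide 1.

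Trpv6, S100g and inflammatory genes were again lower. Trpv6 fell 6.37-fold (-2.67 ± 0.1, adjusted p = 5.58e-06) and S100g 2.03-fold (-1.02 ± 0.09), while Vdr rose by 0.36 ± 0.06 (adjusted p = 0.00468, and 0.458 on the series matrix values) and Cyp24a1 did not pass (0.35 ± 0.46, adjusted p = 0.561). The list of calcium and vitamin D handling did not pass (4 of 17 genes rose and 5 fell, 5 and 6 adjusted over the list alone, adjusted p = 0.385). Mmp7 fell 12.5-fold (-3.64 ± 0.06), Lcn2 16.3-fold (-4.03 ± 0.16), Cxcl5 46.5-fold (-5.54 ± 0.15) and S100a9 11.8-fold (-3.57 ± 0.09). Under normexp correction the last 3 were at -1.91, -3.63 and -2.96. S100a8, not well above background on any array without tumors, was at least 15.2-fold lower (adjusted p = 9.51e-06). Cxcl3 was likewise at least 3.83-fold lower (adjusted p = 8.02e-05), though not under normexp correction (adjusted p = 0.0789), and Ptgs2 fell 2.68-fold (-1.42 ± 0.14). Of 24 inflammation genes 14 fell and 4 rose, of 19 myeloid genes 8 fell, and of 9 mast cell genes 6 fell, the same counts adjusted over the list alone, with Cpa3 (-1.62 ± 0.11) and the histamine-forming enzyme Hdc (-1.59 ± 0.08) among the last. Medians of these 3 lists were -0.6, -0.33 and -1.38 (adjusted p = 0.000791, 0.000212 and 0.00071, and adjusted p = 0.182, 0.453 and 0.182 with an estimated correlation), or -0.54, -0.2 and -1.07 within slide 1. T and NK cell genes rose in 9 of 20 cases and fell in 2, the same counts adjusted over the list alone. The chemokine Ccl5 (1.25 ± 0.08) and the costimulatory receptor Cd27 (0.92 ± 0.07) rose, and the genes that fell were the cytotoxic proteases Gzmb (-1.74 ± 0.16) and Gzma (-2.26 ± 0.4, well above background on 1 array without tumors, adjusted p = 0.388 under normexp correction). That list's median was 0.35 (adjusted p = 0.0304, and adjusted p = 0.58 with an estimated correlation), or 0.28 within slide 1, and its call ended without replicate 1 or 2 of the group without tumors or without DMH replicate 1.

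Among other cell types and functions, adipocyte genes fell in 9 of 11 cases (10 fell and 1 rose adjusted over the list alone), with Adipoq 66.8-fold lower (-6.06 ± 0.83, but -5.44 without replicate 1 of the group without tumors and -3.62 under normexp correction), Car3 42.8-fold lower (-5.42 ± 0.71), Mrap at least 11.3-fold lower (adjusted p = 0.00232) and Cfd, on 2 arrays without tumors well above background, at -6.69 ± 1.6 (adjusted p = 0.0157, and 0.0991 within slide 1). The difference of Cfd was -4.58, -7.84 and -7.64 without replicates 1, 2 and 3 of the group without tumors. Squamous genes fell in 9 of 13 cases (9 fell and 1 rose adjusted over the list alone), including Krt14 (-2.51 ± 0.08) and Krt6a (-1.84 ± 0.11, on 2 arrays without tumors well above background). Smooth muscle genes rose in 10 of 15 cases (13 adjusted over the list alone), such as Des (1.17 ± 0.19), but in 2 within slide 1. Myh11, the smooth muscle myosin heavy chain, rose by 0.92 ± 0.22, but not within slide 1 (0.42, adjusted p = 0.186) nor without replicate 2 of the group without tumors or DMH replicates 2 or 3 (adjusted p = 0.058, 0.0606 and 0.0531). Medians of the 3 lists were -2.96, -1.04 and 0.68 (adjusted p = 0.000159, 0.000269 and 0.000643, and adjusted p = 0.534, 0.455 and 0.635 with an estimated correlation), or -3.07, -1.09 and 0.34 within slide 1. Clock genes rose in 10 of 18 cases and fell in 4, with Per2 4.67-fold higher (2.22 ± 0.1) and Per3 4.2-fold (2.07 ± 0.06). Immediate early genes fell in 9 of 22 and rose in 2, and fatty acid oxidation genes fell in 5 of 20 and rose in 1. These counts were the same adjusted over the list alone. Their medians were 0.75, -0.13 and -0.18 (adjusted p = 0.0304, 0.0304 and 0.0498, and adjusted p = 0.522, 0.455 and 0.738 with an estimated correlation), or 0.77, -0.1 and -0.26 within slide 1. Without DMH replicate 1 none of the 3 passed, and without replicate 3 with tumors the clock and fatty acid calls ended. The fatty acid call also ended without replicate 1 or 3 of the group without tumors or replicate 1 or 2 with tumors.

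The largest rise of a named gene was that of Gdpd3, 106-fold (6.73 ± 0.58, adjusted p = 0.000179, but 5.11 under normexp correction), followed by Camk2n1 (2.66 ± 0.36), Krtap21-1 (2.54 ± 0.59, on 1 DMH array well above background) and Trappc10 (2.51 ± 0.14). Retnlb, a goblet cell peptide, was 4.38-fold higher (2.13 ± 0.42, adjusted p = 0.00741, and 0.0956 within slide 1). H2-Eb2, Myt1l and Hbb-bh1 were not well above background on any DMH array and were at least 1.33-fold, 1.47-fold and 1.83-fold higher (adjusted p = 0.00361, 0.0175 and 0.011), calls that ended under normexp correction (differences of 0.22, -0.24 and 0.33). Myt1l also did not pass within slide 1 (adjusted p = 0.0532). Dera, an aldolase of deoxyribose phosphate, was lower by a log2 difference of -4.36 ± 0.27 and well above background on 1 array without tumors. Prr9, Cacna1f and Cyp2e1, above it on none, were at least 5.64-fold, 6.88-fold and 6.96-fold lower (adjusted p = 3.63e-05, 9.04e-05 and 0.000825). In total 3881 features were higher and 3652 lower, 540 and 613 of them at least 2-fold. Of the calls 51.5% were higher, against 29.3% on the series matrix values, 44.2% after quantile normalization, 46.8% at unadjusted p under 0.05 with 2-fold, 47.9% among the brighter features (a setting chosen after seeing the data) and 48.3% under normexp correction. That correction also put Camk2n1 at 1.77, Krtap21-1 at 0.66, Trappc10 at 1.15, Per3 at 1.06, Cfd at -5.14, Car3 at -4.17 and Dera at -1.46. Sp5 was then at -2.44, Notum -2.35, Trpv6 -1.76, Gzmb -0.76, Hdc -0.8, Cpa3 -0.9, Krt6a -0.6 and Ptgs2 -0.78, and S100a8 (-1.45), Mrap (-1.2), Prr9 (-0.88), Cacna1f (-0.9) and Cyp2e1 (-1.08) lay below their bounds. With the mean of its probes Per2 was at 1.44. Within slide 1 Camk2n1 was at 3.52 and Krtap21-1 at 1.58. Within slide 1, with the spread taken from slides 1 and 2, 5636 passed, 4663 of these in common, and 85.3% of those at least 2-fold apart kept their call. Camera called 16 lists, 5 up and 11 down, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. The fatty acid call also ended after quantile normalization, among probes above background on all 9 arrays, with the replicate block, and, like the clock call, with array weights or only the compared groups. The T and NK cell call ended after quantile normalization, with the mean of the probes and with array weights, and the immediate early call with array weights.

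**Figure D2:**
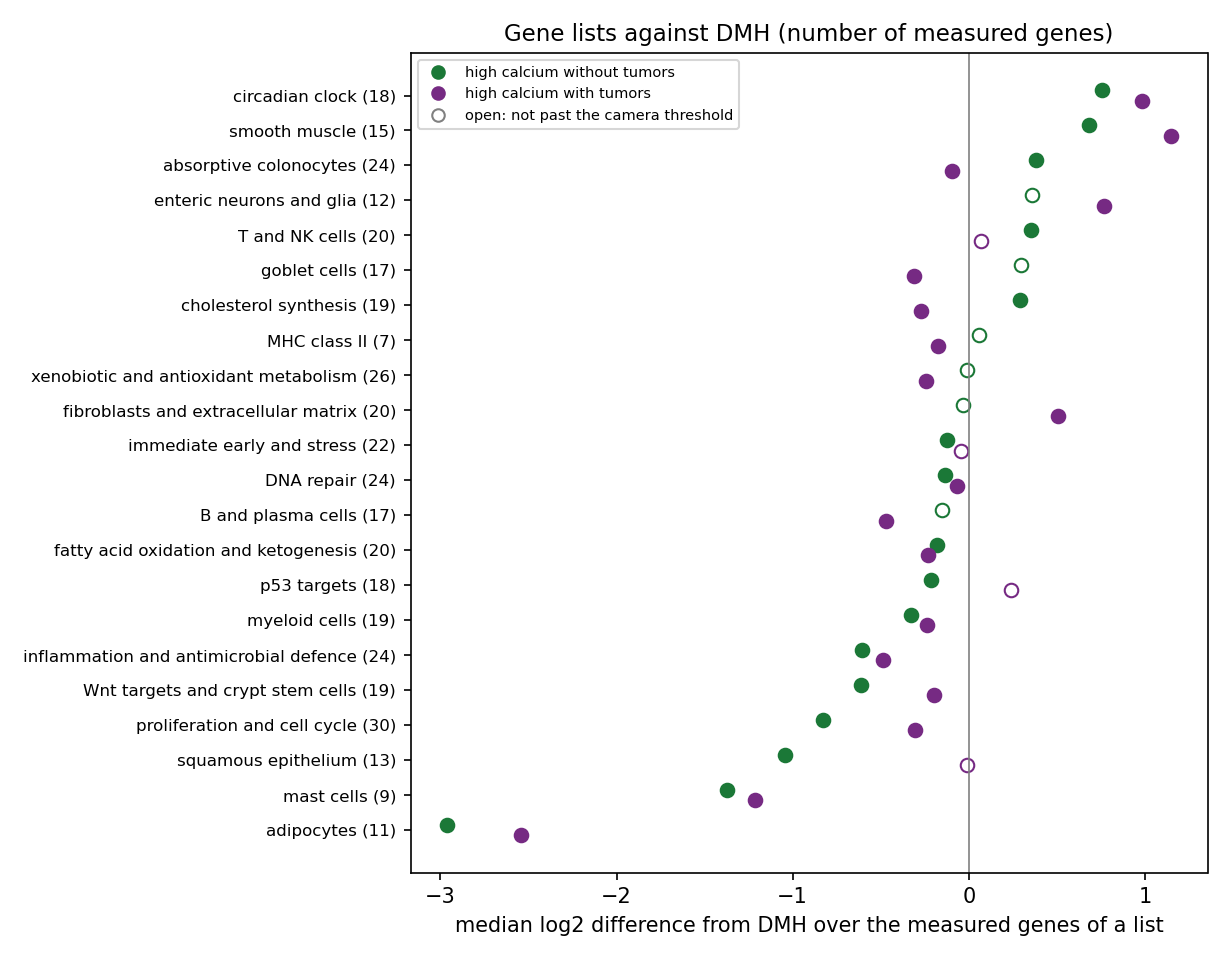
Median log2 difference from DMH of the 22 gene lists past the camera threshold in at least 1 of both comparisons with DMH, with high calcium without tumors in green and with tumors in purple, filled where the list passed and open where it did not. Adipocyte (-2.96 and -2.54) and mast cell genes (-1.38 and -1.22) lie far to the left in both, and colonocyte (0.38 and -0.1) and cholesterol synthesis genes (0.29 and -0.27) lie on opposite sides of 0.

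The third comparison set high calcium mice with tumors against DMH. Fibroblast and smooth muscle genes rose, and B cell and some goblet and absorptive genes fell. Fibroblast and matrix genes rose in 14 of 20 cases and fell in 2, the same counts adjusted over the list alone, with fibronectin, Fn1, 2.3-fold higher (1.2 ± 0.09), vimentin, Vim, 1.94-fold (0.95 ± 0.08) and collagen I, Col1a1, 1.73-fold (0.79 ± 0.06). All 15 smooth muscle genes rose, adjusted over the list alone too, Synm 2.92-fold (1.55 ± 0.23) and calponin, Cnn1, 2.57-fold (1.36 ± 0.2). Medians were 0.51 and 1.15 (adjusted p = 0.000227 and 5.79e-06, and adjusted p = 0.534 for each with an estimated correlation), or 0.54 and 1.36 within slide 2. Of 12 genes of neurons and glia 8 rose (10 adjusted over the list alone), Vip 3.16-fold and Tac1 2.46-fold (1.66 ± 0.1 and 1.3 ± 0.13), with a median of 0.77 (adjusted p = 0.0241, and adjusted p = 0.708 with an estimated correlation), or 0.77 within slide 2, where 2 rose and the list did not pass (adjusted p = 0.0513).

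Goblet cell genes fell in 9 of 17 cases and rose in 4, the same counts adjusted over the list alone. Ang4, an antimicrobial ribonuclease of goblet and Paneth cells, fell 12.6-fold (-3.65 ± 0.09, adjusted p = 5.09e-06), and Spdef, a goblet cell transcription factor, 2.14-fold (-1.1 ± 0.1). Retnlb fell 2.95-fold (-1.56 ± 0.42, adjusted p = 0.0242). That call ended within slide 2 (adjusted p = 0.086), without DMH replicate 1 or 2 (adjusted p = 0.0692 and 0.0622), with the replicate block (adjusted p = 0.0543) and with only the compared groups in the fit (adjusted p = 0.0688). Absorptive colonocyte genes fell in 9 of 24 cases and rose in 3, the same counts adjusted over the list alone, with Cdx2 2.96-fold lower (-1.57 ± 0.08) and Aqp4 2.48-fold lower (-1.31 ± 0.1). Aqp8 (-0.18 ± 0.21, adjusted p = 0.552) and Krt20 (0.04 ± 0.13, adjusted p = 0.847) did not pass. Medians of the goblet and colonocyte lists were -0.31 and -0.1 (adjusted p = 0.0423 and 0.0188, and adjusted p = 0.573 and 0.58 with an estimated correlation), or -0.25 and -0.16 within slide 2, where the goblet list did not pass (adjusted p = 0.314). Leaving out replicate 3 with tumors or DMH replicate 1 or 3 also ended the goblet call, and leaving out DMH replicate 1 the colonocyte call. Cholesterol synthesis genes fell in 12 of 19 cases and rose in 2, the same counts adjusted over the list alone, among them Mvk and Lss (-0.5 ± 0.05 and -0.45 ± 0.05), with a median of -0.27 (adjusted p = 0.00282, and adjusted p = 0.455 with an estimated correlation), or -0.23 within slide 2. Xenobiotic and antioxidant genes fell in 9 of 26 cases and rose in 2 (13 and 3 adjusted over the list alone), with Sult1a1 2.01-fold lower (-1.01 ± 0.11) and Cyp2e1 at least 5.92-fold lower (adjusted p = 0.00241). The median of that list was -0.24 (adjusted p = 0.00998, and adjusted p = 0.472 with an estimated correlation), or -0.16 within slide 2, where it did not pass (adjusted p = 0.0609).

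The falls of proliferation, inflammation and mast cell genes were seen in this group too. Proliferation genes fell in 20 of 30 cases, adjusted over the list alone too, with Top2a 1.95-fold lower (-0.96 ± 0.1) and Ube2c 1.56-fold lower (-0.64 ± 0.09). Mki67 fell 1.29-fold (-0.37 ± 0.09, adjusted p = 0.013, but 0.057 within slide 2 and 0.0983 on the series matrix values). Of 19 Wnt targets and stem cell genes 10 fell and 3 rose (10 and 4 adjusted over the list alone), Sp5 1.5-fold lower (-0.59 ± 0.08) and Lgr5 1.48-fold higher (0.56 ± 0.06). Of 24 DNA repair genes 8 fell and 1 rose, adjusted over the list alone too, Brca1 among the former (-0.57 ± 0.07). Medians of the 3 lists were -0.3, -0.2 and -0.07 (adjusted p = 2.6e-07, 0.0332 and 0.0304, and adjusted p = 0.455, 0.582 and 0.58 with an estimated correlation), or -0.28, -0.23 and -0.03 within slide 2, where the Wnt and repair lists did not pass (adjusted p = 0.0796 and 0.181). Both of these calls ended without replicate 3 with tumors, and the Wnt call without DMH replicate 3. Lgr5 and Myc (-0.39 ± 0.05) passed here but not on the series matrix values (adjusted p = 0.123 and 0.0682). Cdkn1a rose by 0.26 ± 0.08 (adjusted p = 0.0358). The call ended in 6 of the 9 fits without an array, those without replicate 2 of the group without tumors (adjusted p = 0.0515), each array with tumors (adjusted p = 0.0626 to 0.0982) or DMH replicate 2 or 3 (adjusted p = 0.102 and 0.113), and under 5 other settings. Inflammation genes fell in 13 of 24 cases and rose in 4 (14 and 4 adjusted over the list alone), with Cxcl5 16.4-fold (-4.04 ± 0.15), Lcn2 3.42-fold (-1.77 ± 0.16) and Ptgs2 2.48-fold lower (-1.31 ± 0.14). Cxcl3 was at least 3.26-fold lower (adjusted p = 0.000183, but 0.0798 under normexp correction), and Mmp10 and Mmp7 fell 7.37-fold and 3.22-fold (-2.88 ± 0.08 and -1.69 ± 0.06).

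Mast cell genes fell in 5 of 9 cases and rose in 1, adjusted over the list alone too, with Mcpt2 6.55-fold and Mcpt1 4.82-fold lower (-2.71 ± 0.08 and -2.27 ± 0.09). Myeloid genes fell in 10 of 19 cases and rose in 1, adjusted over the list alone too, with S100a9 at -2.64 ± 0.09. Medians of the inflammation, mast cell and myeloid lists were -0.49, -1.22 and -0.24 (adjusted p = 0.000623, 0.000599 and 0.000142, and adjusted p = 0.182, 0.182 and 0.453 with an estimated correlation), or -0.66, -1.15 and -0.22 within slide 2. B and plasma cell genes fell in 13 of 17 cases, adjusted over the list alone too, with the B cell receptor subunit Cd79a 1.87-fold lower (-0.9 ± 0.07) and Mzb1 1.79-fold lower (-0.84 ± 0.08). MHC class II genes fell in 2 of 7 cases, adjusted over the list alone too, H2-DMb1 being one (-0.41 ± 0.06, adjusted p = 0.0567 on the series matrix values). Medians of these 2 lists were -0.47 and -0.18 (adjusted p = 1.64e-06 and 0.0476, and adjusted p = 0.455 and 0.584 with an estimated correlation), or -0.42 and -0.14 within slide 2, where MHC class II did not pass (adjusted p = 0.246). That call ended in 6 of the 9 fits that left out an array, all but those without replicate 3 of the group without tumors, replicate 2 with tumors or DMH replicate 3. Adipocyte genes fell in 8 of 11 cases, with Adipoq 21.9-fold and Car3 15.9-fold lower (-4.45 ± 0.83 and -3.99 ± 0.71). Without replicate 3 with tumors their differences were -5.34 and -4.8, and under normexp correction that of Adipoq was -3.06. Clock genes rose in 10 of 18 and fell in 3 (11 and 3 adjusted over the list alone), with Per2 and Per3 at 1.89 ± 0.1 and 1.56 ± 0.06. Fatty acid oxidation genes fell in 10 of 20 and rose in 1. The adipocyte and fatty acid counts were the same adjusted over the list alone. Their medians were -2.54, 0.99 and -0.23 (adjusted p = 0.000479, 0.00391 and 0.000338, and adjusted p = 0.539, 0.455 and 0.534 with an estimated correlation), or -2.92, 1.03 and -0.27 within slide 2.

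The list of calcium and vitamin D handling did not pass (4 of 17 genes rose and 6 fell, 4 and 7 adjusted over the list alone, adjusted p = 0.387). Of its genes, Trpv6 fell 1.93-fold (-0.95 ± 0.1, adjusted p = 0.000506) and S100g 1.34-fold (-0.43 ± 0.09, adjusted p = 0.00842, and 0.0717 on the series matrix values). Vdr (0.11 ± 0.06, adjusted p = 0.244) and Cyp24a1 (-0.14 ± 0.46, adjusted p = 0.847) did not pass, although Cyp24a1 passed within slide 2 (-0.67, adjusted p = 0.0372) and without replicate 3 with tumors (-0.74, adjusted p = 0.0178). Scnn1g, the gamma subunit of the epithelial sodium channel, rose 7.28-fold (2.86 ± 0.18) and Abcg5 6.27-fold (2.65 ± 0.17), Camk2n1 6.3-fold (2.66 ± 0.36) and Gzmc, a granzyme, 7.37-fold (2.88 ± 0.3). Ciart, a clock repressor, rose by 3.63 ± 0.75 (on 2 DMH arrays well above background), or by 2.69 and 4.34 without DMH replicates 1 and 2. Ptx3, an inflammatory pentraxin, and Wt1, a transcription factor of mesothelium, were not well above background on any DMH array and were at least 4.08-fold and 2.64-fold higher (adjusted p = 0.000273 and 0.000766, but 0.0703 and 0.226 under normexp correction). Apol10a fell 19.3-fold (-4.27 ± 1.01) and Ugt2b38, a glucuronosyltransferase, by 3.86 on the log2 scale (SE 0.79, on 1 array with tumors well above background). Without replicate 3 with tumors these were -5.09 and -4.78, and Apol10a was at -3.63 without replicate 1 with tumors. Zfp945, on 2 arrays with tumors well above background, was 24-fold lower by its brightest probe (-4.58 ± 0.65, adjusted p = 0.00167, or -3.93 and -5.42 without replicates 1 and 2 with tumors), but its other 2 probes went the opposite way, as did the gene on the series matrix values (0.5) and among probes well above background on all 9 arrays (0.63, adjusted p = 0.000831).

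Of the 20 genes taken for the size of their fitted rise or fall, 6 lost their call when a single array was left out. Prg4, not well above background on any DMH array, was at least 4.3-fold higher (adjusted p = 0.0184), with adjusted p = 0.0543 and 0.0511 without replicates 1 and 2 with tumors, 0.0537 without DMH replicate 1 and 0.0716 within slide 2. Prss34, a mast cell protease, was at 2.29 ± 0.56 (on 1 DMH array well above background, 3.02 without DMH replicate 1), with adjusted p = 0.0546 without replicate 2 with tumors, 0.0579 without DMH replicate 3, 0.0527 with only the compared groups in the fit and 0.851 under normexp correction. Car14 was at 2.25 ± 0.56, with adjusted p = 0.0531 and 0.0591 without DMH replicates 2 and 3. Ugt2b5 was at -4.11 ± 1.1 (on 2 arrays with tumors well above background, -3.42, -3.48 and -5.44 without replicates 1, 2 and 3 with tumors), with adjusted p = 0.0712 and 0.0738 without replicates 1 and 2 with tumors and 0.0591 and 0.067 without DMH replicates 2 and 3. Cyp3a25 was at -4.09 ± 1.12 (on 1 array with tumors well above background), with adjusted p = 0.059 to 0.075 without any of those 4 arrays or DMH replicate 1, and 0.0534 within slide 2. Osr2, on 2 arrays with tumors well above background, was at -3.9 ± 1.3 (adjusted p = 0.0499, -4.96 without replicate 3 with tumors), with adjusted p = 0.0674 to 0.141 without any of these 5 arrays or replicate 3 of the group without tumors, and above 0.05 under 4 other settings. In total 4436 features were higher and 3357 lower, 446 and 354 of them at least 2-fold. Of the calls 56.9% were higher, against 39.5% on the series matrix values and 48.9% when every probe was tested. Within slide 2 the differences of Ciart, Prss34, Adipoq, Car3, Apol10a, Ugt2b5, Osr2 and Ugt2b38 were 2.71, 3.13, -5.34, -4.82, -5, -5.58, -4.88 and -4.69. Under normexp correction Ciart was at 1.48, Gzmc 1.32, Scnn1g 1.7, Camk2n1 1.73, Car14 1.2, Per3 0.74, Cxcl5 -3.03, Car3 -3.32, Mcpt2 -1.84 and Lcn2 -1.12. Apol10a was then at -3.1, Zfp945 -2.54, Ugt2b5 -2.38, Osr2 -2.17, Ugt2b38 -1.45, Cyp3a25 -1.3 and Cyp2e1, below its bound, -0.87. With the mean of their probes Per2 and Zfp945 were at 1.18 and -0.97. Within slide 2 (spread from slides 1 and 2) 8965 passed, 6809 of these in common, and 95.9% of those at least 2-fold apart kept their call. Camera called 18 lists, 4 up and 14 down, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. Array weights ended the DNA repair, Wnt, goblet and MHC class II calls. The repair and Wnt calls also ended after quantile normalization and on the series matrix values, and the goblet call with the mean of the probes. Among probes above background on all 9 arrays the goblet and MHC class II calls ended, the second also on the series matrix values and with only the compared groups.

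The fourth comparison set high calcium mice without tumors against high calcium mice with tumors, on the same diet. Absorptive, cholesterol and goblet genes were higher without tumors, and matrix genes and Wnt targets were lower. Colonocyte genes were higher in 16 of 24 cases and lower in 0, with Aqp4 8.49-fold (3.09 ± 0.1), Car4 3.39-fold (1.76 ± 0.11) and Slc9a3, the sodium/proton exchanger, at 2.27 ± 0.5 (on 1 array with tumors well above background, 2.91 without replicate 3 with tumors, adjusted p = 0.113 under normexp correction). Cholesterol synthesis genes were higher in 15 of 19 and lower in 0, such as Mvk (0.88 ± 0.05) and Sqle (0.86 ± 0.04). Goblet genes were higher in 10 of 17 and lower in 1, with Ang4 14.7-fold (3.88 ± 0.09, adjusted p = 2.16e-06) and Retnlb 12.9-fold higher (3.69 ± 0.42). Xenobiotic genes were higher in 13 of 26 and lower in 2, such as Sult1a1 (1.12 ± 0.11) and Ugt2b34 (1 ± 0.09). These counts were the same adjusted over the list alone. The 4 medians were 0.48, 0.42, 0.43 and 0.38 (adjusted p = 4.48e-06, 7.7e-07, 0.0045 and 0.00218, and adjusted p = 0.455, 0.325, 0.46 and 0.455 with an estimated correlation). With the slide as a block they were 0.56, 0.44, 0.15 and 0.3, 7 xenobiotic genes were higher and 1 lower, and the goblet list no longer passed (adjusted p = 0.0818).

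Fibroblast and matrix genes were lower without tumors in 15 of 20 cases, adjusted over the list alone too, with Col1a1 2.81-fold (-1.49 ± 0.06), Col3a1 2.17-fold (-1.12 ± 0.04) and Fn1 2.03-fold lower (-1.02 ± 0.09). Wnt targets and stem cell genes were lower in 12 of 19 and higher in 1 (13 and 1 adjusted over the list alone), with Notum 5.9-fold, Sp5 5.88-fold, Nkd1 3.73-fold and Lgr5 2.35-fold lower (-2.56 ± 0.11, -2.56 ± 0.08, -1.9 ± 0.05 and -1.23 ± 0.06). Of 18 p53 targets 9 were lower (10 adjusted over the list alone), such as Gadd45a (-0.98 ± 0.1) and Plk2 (-0.88 ± 0.11). Medians of the 3 lists were -0.46, -0.37 and -0.27 (adjusted p = 5.79e-06, 0.000159 and 0.00254, and adjusted p = 0.472, 0.455 and 0.46 with an estimated correlation), or -0.62, -0.32 and -0.36 with the slide as a block. Mki67 was lower by -0.46 ± 0.09 (adjusted p = 0.00373, and 0.0541 on the series matrix values). Myc was lower by -0.22 ± 0.05 (adjusted p = 0.0117), but 1 of its other 2 probes went the opposite way, and the call ended with the slide block (adjusted p = 0.083), with the mean of its probes (adjusted p = 0.143) and on the series matrix values (adjusted p = 0.259).

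B and plasma cell genes were higher without tumors in 9 of 17 cases, with Cd79a at 1.09 ± 0.07. T and NK cell genes were higher in 9 of 20 and lower in 3, with Cd27 at 0.68 ± 0.07 and Gzmb at -1.46 ± 0.16. These counts did not differ when adjusted over the list alone. Oxidative phosphorylation genes were higher in 12 of 25 and lower in 2 (13 and 2 adjusted over the list alone), such as Sdha (0.72 ± 0.06). Medians were 0.46, 0.24 and 0.18 (adjusted p = 0.00628, 0.0439 and 0.00496, and adjusted p = 0.58 for each with an estimated correlation), or 0.25, 0.24 and 0.07 with the slide as a block, where oxidative phosphorylation did not pass (adjusted p = 0.195). With the block 4 B and plasma cell, 2 T and NK cell and 5 oxidative phosphorylation genes were higher. Squamous genes were lower in 7 of 13 cases and higher in 1 (7 and 2 adjusted over the list alone), such as Krt15 (-2.22 ± 0.14) and Krt6a (-1.75 ± 0.11, on 2 arrays without tumors well above background). Smooth muscle genes were lower in 5 of 15 (2 adjusted over the list alone), such as Cnn1 (-0.68 ± 0.2, adjusted p = 0.0279, but 0.0685 and 0.0892 without replicates 1 and 3 of the group without tumors, 0.0906 without replicate 2 with tumors and 0.0506 without the filter on dim probes). Medians of both were -0.82 and -0.39 (adjusted p = 0.0182 and 0.0412, and adjusted p = 0.534 and 0.827 with an estimated correlation), or -0.64 and -0.97 with the slide as a block, where 12 smooth muscle genes were lower and the squamous list did not pass (adjusted p = 0.073). Without replicate 3 with tumors these 5 calls all ended, leaving 7 lists. The T and NK cell call also ended without replicate 1 or 2 of the group without tumors, replicate 1 with tumors or DMH replicate 1, and the smooth muscle call without replicate 1 or 3 of the group without tumors or replicate 2 with tumors.

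Trpv6 was 3.29-fold lower without tumors than with tumors (-1.72 ± 0.1), S100g 1.51-fold (-0.59 ± 0.09) and Mmp7 3.88-fold (-1.95 ± 0.06). Vdr was higher by 0.25 ± 0.06 (adjusted p = 0.0143), but not with the slide block (adjusted p = 0.218), under normexp correction (adjusted p = 0.0922), on the series matrix values (adjusted p = 0.399), or without replicate 3 of the group without tumors or replicate 2 with tumors (adjusted p = 0.0502 and 0.0523). Cyp24a1 (0.49 ± 0.46, adjusted p = 0.418) did not pass, but did without replicate 3 with tumors (1.09, adjusted p = 0.00267). Cdkn1a was lower by -0.25 ± 0.08 (adjusted p = 0.0315). The call ended without replicate 1 or 2 of either group (adjusted p = 0.0561 to 0.0977) and under 4 other settings. Aqp8 was higher by 0.85 ± 0.21 (adjusted p = 0.0124, and 0.0596 with the slide block). Krt20 (0.24 ± 0.13, adjusted p = 0.162) passed only in the fits that down-weighted or left out replicate 3 with tumors (adjusted p = 0.0335 without it). Neither Ptgs2 (-0.11 ± 0.14, adjusted p = 0.55) nor Cyp2e1 (adjusted p = 0.185, not well above background in either group) passed, although Cyp2e1 passed after quantile normalization (adjusted p = 0.0454).

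Gdpd3 was 33.2-fold higher without tumors (5.05 ± 0.58, or 5.8 without replicate 2 with tumors) and Mptx1, a pentraxin of the intestinal mucosa, 12-fold (3.59 ± 0.08). Trappc10, the lectin Itln1, the pantothenate kinase Pank3 and the angiogenin Ang2 were 6.48-fold, 6.14-fold, 5.94-fold and 5.72-fold higher (adjusted p at most 0.00113), with Trappc10 and Pank3 well above background on 2 arrays with tumors. Zfp945, on 2 arrays with tumors well above background, was 25.8-fold higher by its brightest probe (4.69, or 4.04 and 5.52 without replicates 1 and 2 with tumors), but its other 2 probes and the gene on the series matrix values (-0.84) and among probes well above background on all 9 arrays (-0.78) went the opposite way, and it did not pass with the slide block (adjusted p = 0.0567). Dera, Cyp2b9 and Adcy8 were at -5.31 ± 0.27, -4 ± 0.32 and -3.71 ± 0.24, each on 1 array without tumors well above background. Gzmc, Tmem245, Ptx3 and Wt1 were not well above background on any array without tumors and were at least 14.5-fold, 5.67-fold, 4.37-fold and 2.82-fold lower (adjusted p at most 0.00144). Under normexp correction the last 3 did not pass (adjusted p = 0.0537, 0.0677 and 0.134). Ciart (-3.65 ± 0.75), Elmo2 (at least 3.83-fold lower, adjusted p = 0.0144) and the mitotic kinase Aurkb (at least 7.3-fold lower, adjusted p = 0.00336) lost their call with the slide as a block (adjusted p = 0.318, 0.706 and 0.0704). The difference of Elmo2 was then 0.08. Elmo2 and Aurkb also lost it under normexp correction (adjusted p = 0.871 and 0.0591). In total 4338 features were higher and 5690 lower without tumors, 637 and 952 of them at least 2-fold. Of the calls 43.3% were higher, against 51.2% with array weights and also when every probe was tested, 53.5% without both DMH replicate 1 and replicate 3 with tumors, and 37% on the series matrix values. The slide block put Ang2 at 4.01 (from 2.52), Dera -4.65, Cyp2b9 -3.13, Tmem245 -1.97, Ciart -0.84, Aurkb -1.01 and Cnn1 -1.36. Under normexp correction Gdpd3 was at 4.18, Trappc10 1.15, Pank3 0.87, Slc9a3 0.39, Dera -2.19, Cyp2b9 -1.13, Adcy8 -1.16 and Ciart -1.48. Sp5 was then at -1.91, Notum -1.87, Trpv6 -1.03, Gzmb -0.64, Krt6a -0.57, Zfp945 2.6 and Gzmc, below its bound, -1.54. With the mean of its probes Zfp945 was at 0.95. With the slide as a block 6320 passed, 5012 in common and of the same sign and 16 of the opposite sign, and 65.1% of those at least 2-fold apart kept their call. Camera called 12 lists, 7 up and 5 down, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. The squamous call also ended under normexp correction, and it and the T and NK cell call on the series matrix values and with array weights. Quantile normalization ended the T and NK cell and oxidative phosphorylation calls, and the mean of the probes the T and NK cell and p53 calls. Among probes above background on all 9 arrays the smooth muscle and squamous calls ended, and with array weights that of B and plasma cells.

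**Figure D3:**
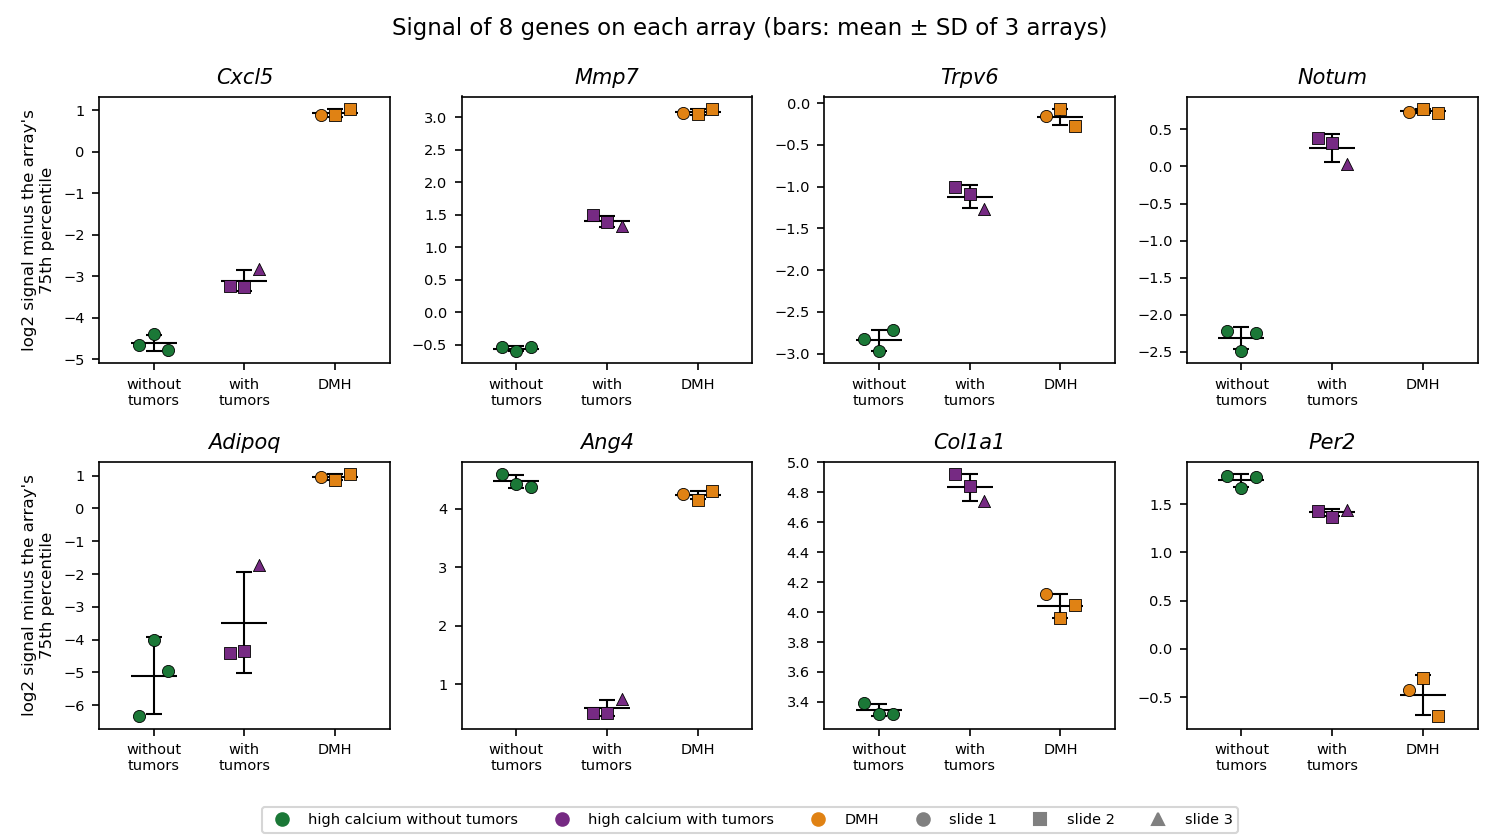
Log2 signal minus the array's 75th percentile for 8 genes on each array, with colour for group, marker shape for slide, and bars for the mean and SD of 3 arrays. Cxcl5, Mmp7, Trpv6 and Notum are highest in DMH and lowest without tumors, Ang4 lies at 4.47 without tumors, 0.59 with tumors and 4.24 in DMH, and Per2 lies at 1.75, 1.42 and -0.48.

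Some other lists passed in no comparison. Against DMH without and with tumors the medians were -0.27 and -0.39 for bile acid handling, 0 and 0.03 for apoptosis, 0.05 and 0.01 for enteroendocrine cells, -0.02 and 0.09 for tuft cells and 0.09 and 0.01 for the interferon response. They were 0.09 and 0.13 for endothelium, 0.19 and 0.03 for exocrine pancreas, 0.37 and 0.43 for small intestine, -0.34 and 0.21 for posterior Hox genes and -0.01 and 0.01 for cell adhesion and tight junctions. Adjusted p ranged from 0.176 to 0.996 over these lists and both comparisons. Of the posterior Hox genes 8 of 12 were lower without tumors than with tumors and 2 were higher, adjusted over the list alone too, with a median of -0.71 (adjusted p = 0.055). Erythroid genes had 3 measured members and were not tested.

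Both comparisons with DMH used the same 3 DMH arrays. Across the 21012 genes with a value on every array their differences correlated at r = 0.327, and the covariance was 0.102. Medians were 0.499 and 0.042 in 20 simulations of all arrays, controls included, as noise of the fitted spread with no gene changed. Within slides 1 and 2, where the comparisons share no array, r was 0.322 and the covariance 0.092. In both comparisons 1513 genes were higher (812 for independent lists of that length, 0 in the simulations) and 1217 lower (581 and 0). Another 1063 went opposite ways (not computed and 0). The 3 controls cannot be split into sets of at least 2, so part of the excess may come from the shared controls.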

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

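The slide tests were chosen after the slide layout and the counts had been seen, those of the slide block against DMH last of all, and the other splits of the arrays before.

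Absorptive colonocyte genes were higher than in DMH without tumors and lower with tumors. The difference between the high calcium groups had a median of 0.479 (adjusted p = 4.48e-06, and 0.455 with an estimated correlation). The fall with tumors (median -0.095) was not called without DMH replicate 1 or among the brighter features. Cholesterol synthesis genes did the same, with a median difference of 0.421 (adjusted p = 7.7e-07, and 0.325 with an estimated correlation).

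Of all 21094 tested, including those without a value on some array, 1069 genes passed in opposite directions against DMH. They also passed between the high calcium groups, which opposite signs nearly ensure. Of these 590 were higher without and lower with tumors, and 479 the reverse. With the slide as a block 519 did so too. An excess over independent lists was not tested. On at least 1 array of every group 1048 were well above background, 508 of them also with the block. Retnlb stood at 2.13 without tumors and -1.56 with tumors against DMH, and Mptx1 at 1.04 and -2.55. The pancreatic lipase relative Pnliprp1 stood at -2.53 and 1.02, and the protease inhibitor Timp1 at -1.09 and 1.16. Mptx1, Pnliprp1 and Timp1 kept all 3 calls with the block, and Retnlb did not. Mptx1 and Timp1 were named after their values were seen.

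The genes at least 2-fold apart were weighed against the slides. With the slide as a block the median of their differences kept 0.95 of its size without tumors against DMH and 1.03 with tumors against DMH. This held among dimmer and brighter genes alike. Between the high calcium groups it kept 0.85 (dimmer) and 0.87 (brighter). The genes were picked by the fit without the block on the same arrays, so these ratios give no verdict on the slides. The calls kept were 82.8 and 93.2%, 94.8 and 98.6%, and 60.8 and 76.5% of the dimmer and brighter genes, so a part of the slides stays open, most of all between the high calcium groups, where the lower quartiles of the ratio were 0.4 and 0.41, against 0.81 to 0.97 in the comparisons with DMH. Genes called without tumors against the 2 DMH arrays of the other slide had the same sign against DMH replicate 1 on their own slide in 89.3% of 1607 cases, with a median ratio of 0.77, and missed by little the share set for that test. In 2481 genes 2-fold apart between replicate 3 with tumors and DMH replicate 1, 65% had the same sign within slide 2, with a median ratio of 0.16. Picked by 1 array against 1, they decide nothing. Slide differences within the tumor and DMH groups correlated at r = 0.574. Diet, tumor burden and animals were not told apart.

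For both high calcium groups against DMH, the 9 arrays were split into 6 and 3 in 84 ways. Of these, 3 gave at least the real 1942 genes of that 2-group fit, a share under the 0.05 set before. The other 2 set apart the 3 arrays without tumors (5344 genes) or the 3 with tumors (5097 genes). Any whole group set apart gave many genes, so this gives no verdict on diet. For the 3 comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real split alone gave 7533, 7793 and 10028 genes, against at most 1, 0 and 1 in the others.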

How the results depend on the processing

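The settings without both DMH replicate 1 and replicate 3 with tumors, of the brighter features and of a single slide were chosen after seeing the data, and the causes of changes were not tested. Of 5484 values of 260 gene results, 5297 stayed on their side of the threshold (32 of them with another sign but no call in either fit), 149 lost the call, 29 gained one and 9 reversed. Folds moved over 1.5 times in 97 of 260 gene results under normexp correction and in 19 with the slide block. Counts are given for both high calcium groups, without tumors and with tumors against DMH, then between the high calcium groups. Genes numbered 3180, 3879, 4156 and 6289 under normexp correction, 2144, 3339, 2403 and 4783 on the series matrix values (fewer probes, and a shift of the median of all genes by -0.177, -0.217, -0.134 and -0.086), and 634, 1362, 879 and 1695 at unadjusted p under 0.05 with 2-fold. Array weights (0.21 for replicate 3 with tumors and 0.24 for DMH replicate 1) gave 10345 and 13034 in the first 2, and the slide block 6320 in the last. Without both of those arrays 12618 genes passed without tumors against DMH and 7 lists between the high calcium groups. Among the brighter features there were 4387 genes in the first and 6451 in the last, with 9 lists each for both groups and with tumors against DMH. Slide 1 alone gave 3704 genes. The other counts stayed within 1.5 times, in 10 of 15, 10 of 16, 13 of 16 and 10 of 15 settings for genes and 13, 13, 13 and 12 of 15 for lists. Lists numbered 0 in all 4 with an estimated correlation and, with fry, 25 without tumors and 19 between the high calcium groups. Leaving out each array gave 4320 to 7474, 5293 to 9427, 5974 to 8052 and 8272 to 12265 genes and 12 to 14, 13 to 17, 14 to 19 and 7 to 14 lists. Replicate numbers do not pair the arrays (r of deviations from -0.567 to 0.221), and the replicate block gave 5190, 5965, 6437 and 8836 genes. Reversed were Myt1l for both groups (-0.01) and without tumors (-0.24) under normexp correction, Zfp945 with tumors (0.5) and between the groups (-0.84) on the series matrix values and with all 9 arrays above background (0.63 and -0.78), Elmo2 between the groups with the slide block (0.08), Clock for both groups with the mean of its probes (0.36), and Wee1, without a call before, for both groups without both of those arrays (-0.37). Among the brighter features the mast cell and inflammation calls ended in all 3 comparisons with DMH. The neuronal, squamous and immediate early calls ended for both groups, and the adipocyte, squamous, immediate early and fatty acid calls without tumors. With tumors the DNA repair, Wnt, xenobiotic, colonocyte, goblet, MHC class II and neuronal calls ended, and between the high calcium groups the B and plasma cell, smooth muscle and squamous calls. Replicate 3 with tumors, on slide 3, lay at least 2-fold from replicates 1 and 2 in 42.9% of the dimmest 2102 genes (median shift 0.64) and 0.9% of the brightest (-0.066).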

Other observations

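The test of pan-epithelial genes was chosen only after the fall it concerns had been seen, and the tests of adenoma and clock output genes before.

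Most genes of Paneth cells, which secrete antimicrobial peptides in the small intestine and appear in inflamed colon, were lower on high calcium. This list was drawn up after most values had been seen, was not tested by camera and shares 4 genes with other lists. Of 11 measured genes 9 fell in the mean of both groups (median -1.87). The defensins Defa31 (-3.3 ± 0.08), Defa22 (-3 ± 0.25, but -1.56 under normexp correction), Defa20 (-2.87 ± 0.09) and Defa23 (-2.54 ± 0.16) fell, whereas the lysozyme gene Lyz1 (-0.23 ± 0.11, adjusted p = 0.144) passed only where DMH replicate 1 was left out or down-weighted (-0.36, adjusted p = 0.019 without it). The medians were -1.88 without tumors (7 genes fell) and -1.93 with tumors (9 fell). Itln1 and Ang4 fell with tumors (-2.45 ± 0.06 and -3.65 ± 0.09), while without tumors their differences from DMH were 0.17 ± 0.06 and 0.23 ± 0.09 (adjusted p = 0.0734 and 0.0829), and the difference between the high calcium groups was 2.62 and 3.88.

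The fall of proliferation and Wnt target genes was weighed against the makeup of the samples. A smaller share of epithelium would lower every epithelial gene. The median of 12 pan-epithelial genes was 0.087 without tumors and 0.12 with tumors against DMH (7 of them also in other lists). No lowering was seen, but chosen afterwards the test gives no verdict. More adenoma-like epithelium in the DMH samples would lower adenoma genes on high calcium. Of 12 measured adenoma genes outside the other lists, 8 fell and 1 rose without tumors (median -0.422). With tumors 5 fell and 1 rose (median -0.306). Sox17 and Bambi fell in both. Both medians lay between the bounds of -0.5 and -0.2 set before. This explanation stays open, as do other shifts in makeup and an effect of the diet.

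The 2 arms of the circadian clock shifted apart on high calcium, with a median of 1.36 over the arm of Per and Dbp (7 of 10 genes rose) and -0.94 over the arm of Arntl (3 of 5 fell and 1 rose, Arntl itself at -1.02 ± 0.06). In the first arm Ciart (1.81 ± 0.65, adjusted p = 0.0726, but 2.29 and adjusted p = 0.00291 with the slide block, and past the threshold also without DMH replicate 2 and at 0.74 under normexp correction), Bhlhe41 (not well above background on any DMH array, adjusted p = 0.339) and Nr1d1 (0.05 ± 0.11, adjusted p = 0.754) did not pass, and in the second Clock did not (-0.05 ± 0.06, adjusted p = 0.528, but 0.36 and adjusted p = 0.0169 with the mean of its probes) and Cry1 rose (0.46 ± 0.13, adjusted p = 0.0361, a call that ended under 6 other settings and in 7 of the 9 fits without an array). A different clock phase when the tissue was taken may account for the shift and predicts a rise of clock output genes outside the lists, and the median of 4 such genes was 0.455 (quartiles 0.013 and 0.931), above the bound of 0.3 set before, but 0.285 with tumors against DMH. Of the 4, Usp2 (1.15 ± 0.15) and Tsc22d3 (0.86 ± 0.06) rose, while Wee1 (0.05 ± 0.38, adjusted p = 0.925, but 0.43 with the slide block and -0.37 without both DMH replicate 1 and replicate 3 with tumors, past the threshold in each) and Lonrf3 (-0.1 ± 0.06, adjusted p = 0.244) did not pass, and Lonrf3 fell without tumors (-0.32 ± 0.07, adjusted p = 0.0101, but 0.0564 within slide 1 and 0.0643 on the series matrix values). The hour at which tissue was taken is not given in the sources used here, and an effect of the diet on the clock was not tested.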
